A study of Homo sapiens with 6 samples.

How the data were processed

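Messenger RNA of untreated MDA-MB-231 cells was sequenced in 6 libraries, 3 of wild-type cells and 3 of cells with the SPHK2 S399A knock-in. Each library was assigned to its group from its sample title, and each column of the expression table was matched to its sample by the column name given in the labels. No column of values was left unused.

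The authors deposited TPM values, which are read counts divided by gene length and scaled to 1000000 per library. Per the submitters' processing notes, the tools listed were FastQC 0.11.8, fastp 0.20.1, HISAT2 2.1.0, featureCounts 1.6.4 and Subread, and the build was hg38; the notes used here give neither their settings nor the gene annotation, and whether strand was used in counting is not given in the sources used here. Overlapping and antisense genes can therefore share reads. Each deposited column sums to 1000000 TPM over the 15177 listed genes, so a rise of some genes lowers the TPM of others. Of 19969 protein-coding symbols of GENCODE release 29, 6293 were not among the listed genes and were not analysed here; these were 27.1% of the symbols that RefSeq still uses and 96.5% of those it no longer uses. No mitochondrially encoded gene and no member of the histone list was among the listed genes, so neither list was tested.

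Within a gene, the TPM values of the 6 libraries are whole multiples of the worth of 1 read. Reads were recovered from these steps for 100% of the genes within 0.01 read, with 14671874 to 15122544 reads per library. On simulated data of 14761 genes the recovery was exact for 97.7% and exact up to a common factor for 100%, so the recovered reads of a few genes are understated. A tested gene had a median of 575 reads per library, and 395 tested genes had under 10 on average. Among highly read genes (at least 3000 reads over the group) the median coefficient of variation was 2.59% in wild type and 2.65% in knock-in libraries, of which counting alone gives 2.28% and 2.26%. Every pair of replicates differed by more than sampling noise (chi-square per gene from 1.63 to 2.56), so no pair was merged as 1 library deposited again. This does not show that the libraries came from separate cultures.

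Because TPM are not counts, the main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), fitted to all 6 libraries with the group as the sole term. Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, which left 11171. Calls were two-sided with a Benjamini-Hochberg adjusted p under 0.05, and a 2-fold change meant an absolute log2 fold change of at least 1. SPHK2 was also tested with an exact permutation test.

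Before the data were examined, 34 gene lists were written from textbook knowledge, and the 28 with at least 5 tested members were tested with camera at a correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 28. The lists are those named in the results, together with the mitochondrially encoded and histone lists. Named genes followed a rule fixed at the same time: SPHK2; the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 TPM in a group and groups that did not overlap; up to 4 called members with the largest change per list; up to 4 genes with the smallest adjusted p per chromosome block; and HDAC1, HDAC2, TERT, CDKN1A, PRKAA1 and PRKAA2 whatever their change. Of the genes that this rule chose from the lists, 1 is not reported here.

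Gene positions came from GENCODE release 29, on the same build as the deposited values, by gene symbol; 11142 of the 11171 tested genes had a position. For each window of 10 Mb with at least 10 tested genes, the median log2 fold change was compared with 10000 random sets of as many tested genes, and p-values were adjusted over 280 windows. Neighbouring windows that moved the same way are described as a block. The edited codon was located by translating the annotated SPHK2 transcripts, taking the numbering of the 654-residue proteins.

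The fits were tested on simulated reads for the 6 libraries before use. Of 50 simulated genes per fold size, the test for S399A against wild type called 54% at 1.2-fold, 92% at 1.5-fold, 98% at 2-fold and 98% at 3-fold among 11194 genes tested, and 16 of 10994 unchanged genes were called, which were 8.56% of all calls. A raised list was called and 0 of 27 unchanged lists were. With no shift 0 of 280 windows were called, and both of 2 shifted windows were. Genes were simulated independently of each other, so these results do not show how the list and window tests behave when genes are correlated. Most simulated genes were also unchanged, whereas 52.3% of the tested genes were called in the data. The simulated spread beyond counting was the same for all genes and close to that of highly read genes (1.41% in wild type, 1.53% in knock-in libraries). It was not measured in genes with fewer reads, so the simulated shares of called genes may be too high for them.

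Alternatives covered the pseudocount (0.1 and 5), the filter (none, and 5 TPM), scaling (trimmed-mean factors, quantile normalization, median centring), the variance model, an adjusted p of 0.01, windows of 5 and 20 Mb, a term for the replicate number and leaving out each library. Alternatives chosen after seeing the data were limma-voom on the recovered reads, centring each gene on its 10 Mb window, keeping only genes outside the windows that moved, and regressing out GC content and exonic length. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.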

Results

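RNA sequencing compared wild-type MDA-MB-231 cells with MDA-MB-231 cells carrying a knock-in of SPHK2 S399A, in which a serine of sphingosine kinase 2 is replaced by alanine. MDA-MB-231 is an established human line of triple-negative breast cancer with mesenchymal features. SPHK2 phosphorylates sphingosine to sphingosine 1-phosphate (S1P), and the series title places the comparison in the regulation of SPHK2 by AMPK, the energy-sensing kinase, and in nuclear S1P signalling. Each group had 3 libraries, none from treated cells, and the labels do not say whether the 3 came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Expression was given for 15177 genes as TPM, transcript abundance scaled to a sum of 1000000 per library, and the steps between TPM values corresponded to 14671874 to 15122544 reads per library. Levels below are means ± SD of n = 3 libraries per group, wild type first, and fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low levels.

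SPHK2 transcript was lower in the knock-in cells, at 18.6 ± 0.047 to 13.7 ± 0.92 TPM (SD, n = 3 per group), a ratio of 0.739. The log2 fold change was -0.41 with a standard error of 0.063 (limma adjusted p = 9.4e-04). All 3 knock-in libraries lay below all 3 wild-type libraries, and an exact two-sided permutation test of the TPM values gave p = 0.1, the smallest p that 3 against 3 libraries allow. SPHK2 lies on the plus strand of chromosome 19 at 48619291 to 48630717 (hg38). By annotation RPL18 ends at 48619536 and DBP starts at 48630030, so both overlap the ends of SPHK2. RPL18 was far more abundant and also fell, from 717 to 622 TPM. Whether strand was used in counting is not known, so the SPHK2 level may include shared reads. In the annotated proteins of 654 residues the edited position is a serine, and its codon occupies positions 48629003 to 48629005 in the last of 7 exons. This codon rests on the numbering of those proteins, which the labels do not give: the other complete annotated proteins that reach the position, of 448, 595, 618 and 663 residues, have no serine there. The table holds transcript levels and no sequence, so it does not check the codon itself.

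HDAC1 and HDAC2, histone deacetylases known to bind nuclear S1P, were both higher in the knock-in cells. HDAC1 went from 297 ± 5.0 to 357 ± 7.0 TPM (limma log2 fold change 0.26, SE 0.025, adjusted p = 8.2e-05) and HDAC2 from 84.9 ± 2.0 to 98.7 ± 1.9 TPM (0.22, SE 0.032, adjusted p = 8.2e-04). CDKN1A, which encodes the cell-cycle inhibitor p21, rose from 48.2 ± 2.6 to 113 ± 5.6 TPM (1.22, SE 0.051, adjusted p = 2.1e-06). TERT, the catalytic subunit of telomerase, was at a low level and fell from 3.31 ± 0.73 to 1.59 ± 0.84 TPM (-0.77, SE 0.24, adjusted p = 0.026). The 2 catalytic subunits of AMPK moved by small amounts in opposite directions, PRKAA1 from 175 ± 3.0 to 163 ± 2.4 TPM (-0.10, adjusted p = 0.011) and PRKAA2 from 24.8 ± 1.7 to 28.6 ± 1.6 TPM (0.20, adjusted p = 0.033). The PRKAA1 call was lost with trimmed-mean scaling (log2 fold change -0.060, adjusted p = 0.094) and with median centring (-0.043, adjusted p = 0.22). The TERT call was lost without wild-type replicate 1 or 3 or knock-in replicate 1 or 3 (log2 fold change from -0.81 to -0.59, adjusted p from 0.051 to 0.083), and also with no filter on low values (adjusted p = 0.051). The PRKAA2 call was lost without wild-type replicate 1 or 2 or knock-in replicate 2 or 3 (log2 fold change from 0.16 to 0.21, adjusted p from 0.060 to 0.10). It was also lost with no filter on low values (adjusted p = 0.056) and with a replicate block (0.066).

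**Figure D1:**
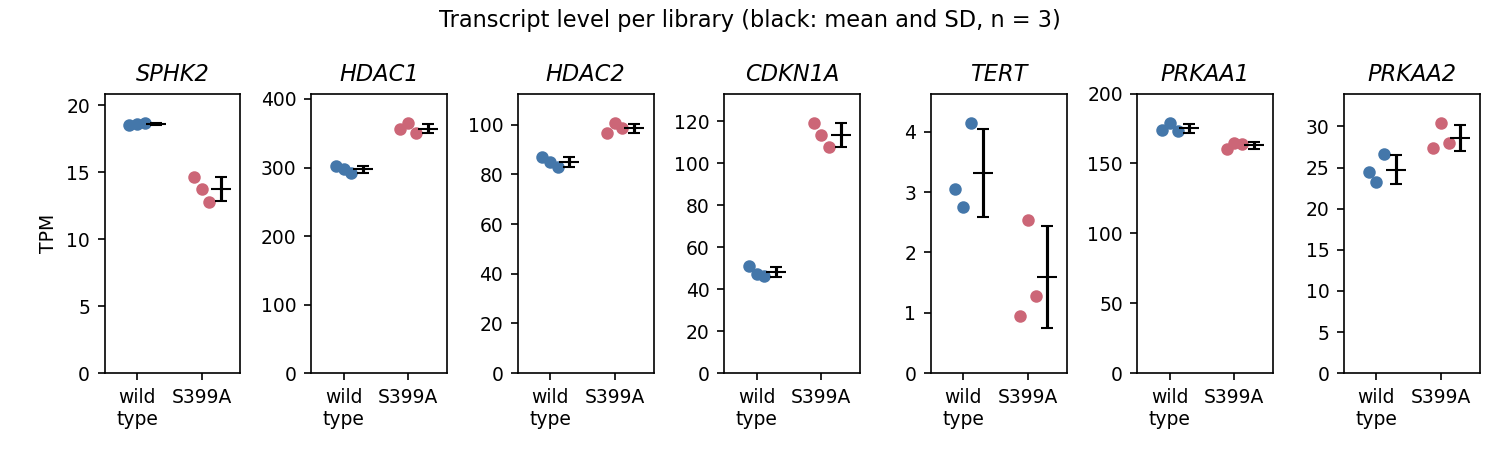
TPM of SPHK2, HDAC1, HDAC2, CDKN1A, TERT, PRKAA1 and PRKAA2 in each library, with wild type in blue and S399A in red, each panel on its own linear axis from 0. Black bars give the mean and SD of n = 3 libraries; the 3 S399A libraries lie below the wild-type libraries for SPHK2 and above them for HDAC1, HDAC2 and CDKN1A.

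The question of the main comparison was which transcripts differ when SPHK2 lacks this serine. Individual cytokine, cancer-testis and stress genes were among those with the largest changes. As a list, NF-kB and cytokine genes had no call (camera adjusted p = 0.35). X-linked cancer-testis families, tested only after the data were seen, had none either, with 4 of 11 genes higher and 2 lower (camera adjusted p = 0.37). IL1B, an inflammatory cytokine, rose from 1.42 ± 0.52 to 17.01 ± 1.0 TPM (log2 fold change 2.91, SE 0.15), while the chemokine CCL2 fell from 19.99 ± 2.0 to 1.53 ± 0.33 TPM (-3.06, SE 0.12). PAPPA2, a protease of insulin-like growth factor binding proteins, rose from 0.1105 ± 0.046 to 7.45 ± 0.66 TPM, and FST, the activin antagonist follistatin, fell from 154 ± 4.8 to 28.2 ± 1.0 TPM. CHAC1, a glutathione-degrading enzyme of the stress response, rose from 6.04 ± 1.4 to 32.6 ± 2.9 TPM, and HSPB8, a small heat-shock protein, rose from 10.3 ± 1.1 to 50.8 ± 1.6 TPM.

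Among the 12 largest rises, S100P rose from 2.32 ± 1.6 to 18.7 ± 2.7 TPM and TCN1, a cobalamin binder, from 0.875 ± 0.57 to 7.696 ± 1.3 TPM. TFF1, a secreted trefoil peptide, rose from 0.889 ± 0.38 to 9.38 ± 0.71 TPM, on 1.33 and 14 reads per library on average. The decoy receptor IL13RA2 rose from 0.135 ± 0.12 to 7.78 ± 2.6 TPM, with 0.667 reads per wild-type library on average. The cancer-testis genes SSX1 and SPANXC went in opposite directions, from 8.96 ± 0.89 to 60.5 ± 1.3 TPM and from 60.4 ± 11 to 0.806 ± 0.80 TPM. Both belong to families of near-identical copies, so their levels are uncertain. PIK3AP1, an adaptor of PI3K signalling, fell from 8.42 ± 0.60 to 0.522 ± 0.15 TPM. DCLK1, a microtubule-associated kinase, fell from 5.46 ± 0.16 to 0.474 ± 0.067 TPM. The focal adhesion protein TNS4 fell from 20.3 ± 1.3 to 3.92 ± 0.46 TPM and the secreted epidermal protein DMKN from 13.2 ± 0.92 to 1.87 ± 0.21 TPM. The pseudogenes UBBP4 (37.6 ± 0.95 to 0.464 ± 0.27 TPM) and HNRNPA1P33 (27.1 ± 7.8 to 2.94 ± 1.0 TPM) can share reads with their parent genes and are uncertain. The other genes on both lists are the microRNA genes MIR5685, MIR103A2, MIR210, MIR3192, MIR2116 and MIR3671. They had at most 5 reads per library on average in either group. For MIR210, MIR2116 and MIR3671 the nearest libraries of the groups held equal reads. The groups of these genes were apart only through library scaling, as for MIR3671 at 3.7776 TPM in wild-type replicate 2 and 3.7185 TPM in knock-in replicate 2. Limma adjusted p lay between 1.2e-07 for FST and 0.016 for MIR3671 among these 24 genes. With robust variances the calls of MIR210, MIR2116 and MIR3671 were lost at the same fold changes (adjusted p = 0.079, 0.073 and 0.077). The MIR3671 call was also lost without wild-type replicate 1 or knock-in replicate 1 or 3 (adjusted p from 0.052 to 0.055) and with recovered reads (0.069).

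Of 11171 tested genes, 2451 rose and 3391 fell (limma, Benjamini-Hochberg adjusted p under 0.05), together 52.3%. Most changes were small, since 80.3% of the changed genes moved by less than 1.5-fold, and 98 genes rose and 213 fell by at least 2-fold. For 6828 genes (61.1%) the libraries of the groups did not overlap, where chance gives 10%. Rising genes made up 42.0% of the changed genes on the deposited scale, 51.2% with trimmed-mean scaling, 51.2% with quantile normalization and 55.0% with median centring, so the balance of rises and falls depended on the scaling. The count at 2-fold depended on the pseudocount, with 492 genes at 0.1 and 102 at 5. Correlations of log2 values across genes lay between 0.9893 and 0.9916 within a group and between 0.9752 and 0.9762 between groups, and the first principal component, which separated the groups, held 60.6% of the variance.

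**Figure D2:**
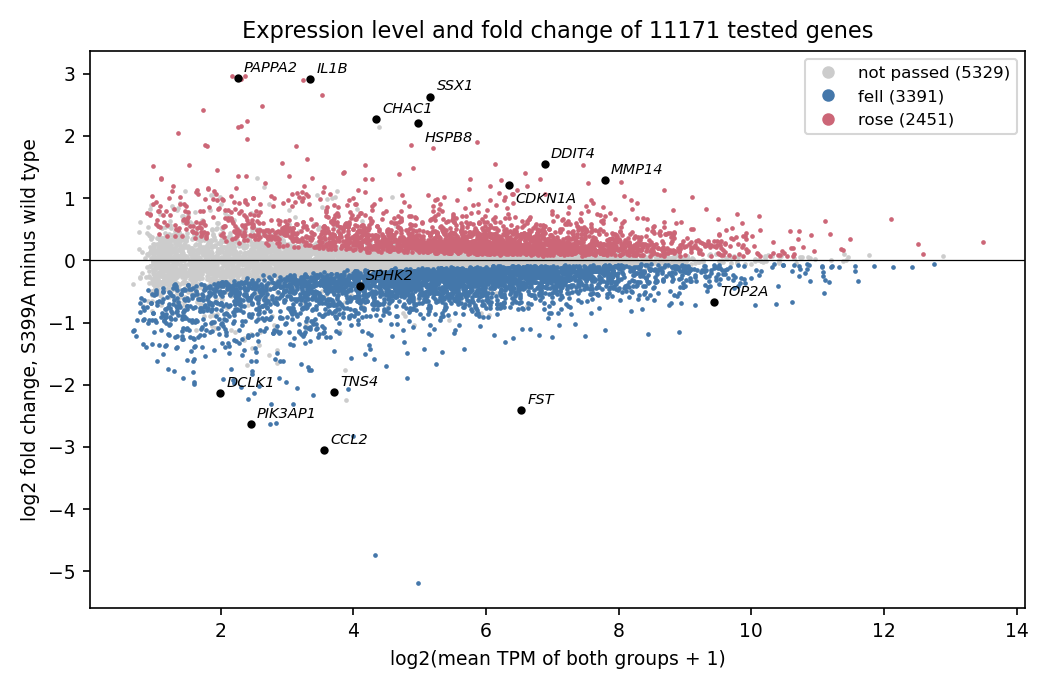
Log2 fold change (S399A minus wild type, on the log2(TPM + 1) scale) against the log2 mean level of 11171 tested genes, with the 2451 that rose in red, the 3391 that fell in blue and the rest in grey. Most coloured points lie close to 0, and black points mark genes that the text names, such as IL1B and CCL2.

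The hypoxia response and glycolysis lists rose in the knock-in cells. Of 19 tested hypoxia genes 15 rose and 1 fell, with a median log2 fold change of 0.40 (camera adjusted p = 1.8e-06; adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, 16 rose and 1 fell. DDIT4, an inhibitor of mTORC1, rose from 59.6 ± 1.4 to 175 ± 4.6 TPM (limma adjusted p = 3.2e-07). The angiogenic factor VEGFA rose from 42.4 ± 2.0 to 105 ± 1.1 TPM. NDRG1 rose from 53.98 ± 0.96 to 115 ± 3.2 TPM and ANGPTL4 from 10.3 ± 1.4 to 20.5 ± 4.7 TPM. Of 20 glycolysis genes 14 rose and 2 fell, with a median of 0.29 (camera adjusted p = 2.1e-05; adjusted p = 0.26 with an estimated correlation). Adjusted over the list alone, 15 rose and 2 fell. PDK1, which restrains entry of pyruvate into the mitochondrion, rose from 12.9 ± 0.42 to 24.96 ± 0.98 TPM. The glycolytic enzymes PGK1, ENO2 and PFKL rose with log2 fold changes of 0.75, 0.63 and 0.60. These cells were untreated, so no library in the series measures the response to low oxygen or glucose.

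Stress-response, antioxidant and lysosomal genes also rose as sets. Among 21 genes of the integrated stress and unfolded protein responses 14 rose and 3 fell, with a median of 0.46 (camera adjusted p = 0.0011; adjusted p = 0.21 with an estimated correlation). Adjusted over the list alone, 14 rose and 5 fell. Beside CHAC1, the lipoprotein receptor VLDLR rose from 6.64 ± 0.36 to 14.1 ± 0.12 TPM. PHGDH, the first enzyme of serine synthesis, rose from 18.3 ± 1.7 to 30.6 ± 1.5 TPM. SDF2L1, an endoplasmic reticulum chaperone component, fell from 93.1 ± 3.2 to 58.2 ± 9.8 TPM. Among 26 NRF2 targets 16 rose and 2 fell, or 16 and 3 adjusted over the list alone (median 0.23, camera adjusted p = 1.8e-04; adjusted p = 0.21 with an estimated correlation). The aldo-keto reductases AKR1C3 and AKR1B1 rose from 13.2 ± 0.60 to 36.3 ± 2.4 TPM and from 154 ± 8.2 to 279 ± 8.7 TPM. AKR1B10 rose from 0.433 ± 0.22 to 4.34 ± 1.8 TPM, and heme oxygenase HMOX1 rose from 24.9 ± 1.3 to 46.5 ± 1.2 TPM. AKR1C3 and AKR1B10 have close paralogs, so their levels are uncertain where reads could be split.

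Of 25 immediate early genes 16 rose and 3 fell, or 17 and 3 adjusted over the list alone (median 0.28, camera adjusted p = 4.9e-04; adjusted p = 0.43 with an estimated correlation). The transcription factor genes JUNB and KLF4 rose from 53.5 ± 3.7 to 112 ± 1.9 TPM and from 46.5 ± 2.7 to 74.2 ± 1.7 TPM, IER2 rose with a log2 fold change of 0.76, and ETV4 fell with one of -0.69. Of 23 lysosome and autophagy genes 12 rose and 5 fell (median 0.16, camera adjusted p = 0.011; adjusted p = 0.21 with an estimated correlation). The lysosomal protease CTSD rose from 57.7 ± 2.4 to 111 ± 1.6 TPM, and the autophagosome proteins GABARAPL1 and MAP1LC3B rose from 25.9 ± 1.9 to 45.7 ± 2.2 TPM and from 101 ± 3.7 to 166 ± 6.4 TPM. BECN1, which starts autophagosome formation, fell from 60.2 ± 1.8 to 36.9 ± 1.2 TPM.

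The DNA replication and mitosis list was the only list that camera called lower with the preset correlation. Of 35 tested genes 23 fell and 5 rose, or 24 and 5 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0042; adjusted p = 0.28 with an estimated correlation). Topoisomerase TOP2A fell from 854 ± 7.2 to 536 ± 4.8 TPM (limma adjusted p = 5.7e-07). The mitotic kinase AURKB fell from 244 ± 15 to 166 ± 2.8 TPM. The mitotic motor KIF11 fell from 419.9 ± 9.0 to 286 ± 6.9 TPM and the replicative helicase subunit MCM7 from 566 ± 7.6 to 392 ± 10.1 TPM. All 4 of these genes, and 10 of the 23 that fell, lie in chromosome windows whose genes were lower as a whole. Of 25 telomerase and c-MYC targets 13 fell and 4 rose (camera adjusted p = 0.056). This list passed with quantile normalization (0.023), with no filter on low values (0.027), without wild-type replicate 1 (0.0499), centred on windows (0.026) and with recovered reads (0.011). The nucleolar protein genes NOP56 and MYBBP1A fell from 448 ± 7.0 to 289 ± 5.1 TPM and from 169 ± 7.9 to 112 ± 1.4 TPM. The pyrimidine synthesis enzyme CAD fell from 118 ± 1.9 to 81.2 ± 5.1 TPM. Of 17 p53 targets 4 rose and 3 fell (camera adjusted p = 0.2). On this list were CDKN1A, TNFRSF10B (0.54) and PMAIP1 (0.52) higher and BTG2 lower (-1.26).

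Adhesion and TGF-beta genes rose as sets, while epithelial and mesenchymal identity genes went both ways. Of 20 TGF-beta and SMAD targets 13 rose and 5 fell, or 13 and 6 adjusted over the list alone (median 0.35, camera adjusted p = 0.018; adjusted p = 0.28 with an estimated correlation). With median centring the list no longer passed (median 0.41, camera adjusted p = 0.052). LTBP3, which holds latent TGF-beta, rose from 24.5 ± 0.54 to 48.9 ± 3.5 TPM and the activin subunit INHBA from 3.45 ± 0.27 to 6.64 ± 0.67 TPM, against the fall of FST. Of 20 integrin and focal adhesion genes 11 rose and 4 fell (median 0.15, camera adjusted p = 0.023; adjusted p = 0.60 with an estimated correlation). ITGA5, the fibronectin receptor subunit, rose from 45.98 ± 0.96 to 98.1 ± 3.8 TPM and lies in a chromosome window whose genes were higher as a whole. ITGB4 rose from 92.2 ± 5.3 to 160.4 ± 3.1 TPM and ITGB1 from 325 ± 5.9 to 496 ± 4.1 TPM. TNS1 fell with a log2 fold change of -0.98.

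Of 29 extracellular matrix and protease genes 16 rose and 8 fell, or 17 and 8 adjusted over the list alone (camera adjusted p = 0.056). The collagenase activator MMP14 rose from 127 ± 5.9 to 313 ± 7.0 TPM and the protease inhibitor TIMP3 from 48.9 ± 1.1 to 91.9 ± 2.6 TPM. The collagen COL8A1 fell from 14.96 ± 0.81 to 6.53 ± 0.61 TPM and MMP3 from 3.96 ± 0.33 to 1.48 ± 0.093 TPM. Of 18 mesenchymal genes 9 rose and 5 fell (camera adjusted p = 0.089). Fibronectin FN1 rose from 128 ± 5.6 to 234 ± 9.7 TPM and S100A4 from 15.3 ± 1.9 to 26.5 ± 0.58 TPM. The transcription factor PRRX1 fell with a log2 fold change of -0.65. Of 11 epithelial genes 4 rose and 3 fell (camera adjusted p = 0.46). Keratin KRT19 fell from 177 ± 4.0 to 74.8 ± 7.6 TPM and EPCAM from 9.47 ± 1.6 to 4.25 ± 1.4 TPM. The claudin CLDN3 fell from 3.78 ± 0.11 to 0.258 ± 0.26 TPM. SPINT2 rose from 182 ± 4.4 to 252 ± 1.9 TPM. Of 23 YAP and TEAD targets 5 rose and 11 fell, or 5 and 12 adjusted over the list alone (camera adjusted p = 0.32). Tissue factor F3 fell from 607 ± 12 to 376 ± 7.4 TPM and ANKRD1 from 754 ± 17 to 535 ± 7.4 TPM. IGFBP3 and NUAK2 fell with log2 fold changes of -0.48 and -0.76. The epithelial list had a positive median and a negative mean.

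Genes of sphingolipid metabolism and of S1P transport had no camera call as lists, while fry called both lower (adjusted p = 0.019 and 0.018). Of 31 tested sphingolipid genes 6 rose and 10 fell (camera adjusted p = 0.89). SGPL1, the lyase that degrades S1P, fell from 45.8 ± 1.6 to 28.2 ± 0.080 TPM (log2 fold change -0.68, limma adjusted p = 1.0e-05). The S1P phosphatase SGPP2 fell from 2.63 ± 0.47 to 1.19 ± 0.32 TPM and the ceramidase ASAH2 from 1.54 ± 0.23 to 0.558 ± 0.33 TPM. SPTLC3, a subunit of the enzyme that starts sphingolipid synthesis, rose from 22.6 ± 0.91 to 34.1 ± 0.32 TPM. Of 9 S1P receptors and transporters 1 rose and 4 fell (camera adjusted p = 0.51). The receptor S1PR3 fell from 11.8 ± 1.1 to 7.78 ± 0.54 TPM and S1PR1 from 1.39 ± 0.29 to 0.673 ± 0.22 TPM. The S1P exporter SPNS2 fell from 1.64 ± 0.25 to 0.674 ± 0.26 TPM, and the lipid transporter ABCA1 rose from 3.23 ± 0.40 to 6.296 ± 0.12 TPM. The S1PR1 call rested on 22 and 10.7 reads per library and was lost with trimmed-mean scaling (adjusted p = 0.0503), quantile normalization (0.13), median centring (0.065), a pseudocount of 0.1 (0.054) or a replicate block (0.091), and without knock-in replicate 2 (0.079) or 3 (0.12). For the sphingolipid list the median and mean were negative while the camera statistic pointed up.

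Of 17 AMPK subunits and upstream kinases 3 rose and 4 fell (camera adjusted p = 0.88). The stress sensor SESN3 fell from 11.5 ± 0.59 to 4.68 ± 0.22 TPM and FLCN fell with a log2 fold change of -0.42. MAP3K7 and CAB39 rose by log2 fold changes of 0.38 and 0.28. Of 30 histone deacetylases and acetyltransferases 6 rose and 11 fell, or 6 and 13 adjusted over the list alone (camera adjusted p = 0.54). The acetyltransferases KAT2A and KAT7 fell from 92.02 ± 1.4 to 50.3 ± 2.8 TPM and from 23.3 ± 0.67 to 14.3 ± 0.71 TPM. The deacetylases HDAC5 and SIRT1 fell from 14.3 ± 0.57 to 8.21 ± 0.44 TPM and from 84.4 ± 3.1 to 56.4 ± 3.2 TPM. Of the 11 that fell, 7 lie in windows whose genes were lower as a whole.

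Cholesterol synthesis was the lipid list that rose. Of its 20 tested genes 11 rose and 1 fell (median 0.17, camera adjusted p = 0.018; adjusted p = 0.22 with an estimated correlation). MVD rose from 44.6 ± 1.8 to 61.6 ± 2.9 TPM, MSMO1 from 261 ± 0.92 to 342 ± 6.2 TPM and IDI1 from 137 ± 1.2 to 179 ± 4.4 TPM. Of 16 genes of fatty acid synthesis and desaturation 4 rose and 8 fell, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.88). ACLY, which makes cytosolic acetyl-CoA, fell from 544 ± 12 to 337 ± 5.6 TPM. Fatty acid synthase FASN fell from 322 ± 4.5 to 275 ± 12 TPM and ACACB from 5.63 ± 0.69 to 3.29 ± 0.51 TPM. Malic enzyme ME1 rose from 60.7 ± 3.3 to 89.6 ± 1.6 TPM. Of 20 genes of fatty acid oxidation 5 rose and 5 fell, or 6 and 6 adjusted over the list alone (camera adjusted p = 0.88). The carnitine palmitoyltransferases CPT1A and CPT1C fell with log2 fold changes of -0.44 and -0.95. ETFA fell (-0.38) and ETFB rose (0.55).

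Of 28 nuclear-encoded genes of oxidative phosphorylation 8 rose and 7 fell (camera adjusted p = 0.62). NDUFA1 and COX7C were higher (0.38 and 0.32), and NDUFB8 and COX5A were lower (-0.53 and -0.42). Of 36 cytosolic ribosomal protein genes 8 rose and 16 fell (camera adjusted p = 0.54). RPL23, RPL19, RPL27 and RPL4 fell with log2 fold changes of -0.72, -0.70, -0.67 and -0.53. All 4, and 10 of the 16 that fell, lie in chromosome windows whose genes were lower as a whole. Ribosomal protein genes have many processed pseudogenes, so their levels are uncertain. This list took 5.45% ± 0.085 of all TPM in wild-type and 5.15% ± 0.076 in knock-in libraries (SD, n = 3). The oxidative phosphorylation list had a median and mean just below 0 with a camera statistic that pointed up.

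Cytokine and interferon genes changed in both directions. Of 23 NF-kB and cytokine genes 7 rose and 6 fell (camera adjusted p = 0.35). Beside IL1B and CCL2 the growth factor gene CSF2 rose from 6.399 ± 0.87 to 14.9 ± 3.3 TPM and IL1A from 1.63 ± 0.59 to 4.09 ± 0.29 TPM. Of 29 interferon-stimulated genes 8 rose and 11 fell (camera adjusted p = 0.66). IFIT1 fell from 80.2 ± 3.9 to 42.3 ± 4.2 TPM, OAS3 from 16.8 ± 1.4 to 8.71 ± 0.081 TPM and OAS1 from 1.21 ± 0.13 to 0.135 ± 0.030 TPM. IFI44L rose from 1.06 ± 0.15 to 4.61 ± 0.27 TPM. The interferon list had a positive median and a negative mean. Only 2 antigen presentation genes were tested, too few for a set test. The proteasome subunit PSMB10 rose from 3.62 ± 0.58 to 5.64 ± 0.50 TPM and NLRC5 from 5.75 ± 0.37 to 6.91 ± 0.14 TPM. The NLRC5 call (adjusted p = 0.048) was lost without any 1 of the 6 libraries (adjusted p from 0.072 to 0.14) and under other alternatives.

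Markers of other cell types were mostly near the floor. Of the listed leukocyte, fibroblast and endothelial markers, 5 of 9, 3 of 6 and 6 of 8 had means under 1 TPM in both groups. LCP1, an actin-bundling protein of leukocytes that many cancer lines also express, rose from 34.8 ± 0.17 to 104 ± 3.3 TPM. The junction protein ESAM rose from 129 ± 6.4 to 197 ± 1.9 TPM, while COL1A1 fell from 8.01 ± 1.0 to 5.06 ± 0.22 TPM and TAGLN from 2.12 ± 0.037 to 1.24 ± 0.19 TPM. The TAGLN call was lost with quantile normalization (adjusted p = 0.074) and without wild-type replicate 1 (0.052) or 3 (0.053). Of 12 luminal breast markers 4 rose and 4 fell (camera adjusted p = 0.54). Beside TFF1 and KRT19, the transcription factor SPDEF rose from 9.34 ± 1.7 to 19.2 ± 1.0 TPM and the receptor ERBB3 fell from 2.45 ± 0.067 to 0.947 ± 0.14 TPM.

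Over all 28 lists with at least 5 tested members, 10 moved as a set by camera with a preset correlation of 0.01, of which 9 rose and 1 fell. None of the 28 passed with an estimated correlation, while fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, gave 25, with 14 higher and 11 lower. By camera, extracellular matrix and proteases passed under 7 alternatives, telomerase and c-MYC targets under 5, mesenchymal genes under 4, and luminal markers and p53 targets under 1 each, none of which passed in the main fit. Among genes outside the chromosome windows that moved, 3 lists no longer passed with fewer members and similar medians. These were lysosome and autophagy (23 to 14 genes, median 0.16 to 0.13, camera adjusted p = 0.062), cholesterol synthesis (20 to 14 genes, 0.17 to 0.19, adjusted p = 0.084) and integrins (20 to 13 genes, 0.15 to 0.14, adjusted p = 0.097). All 3 kept the call when each gene was centred on its window (camera adjusted p from 0.0029 to 0.0037). For the lists with no second count here, the numbers adjusted over the list alone equalled those over all genes.

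**Figure D3:**
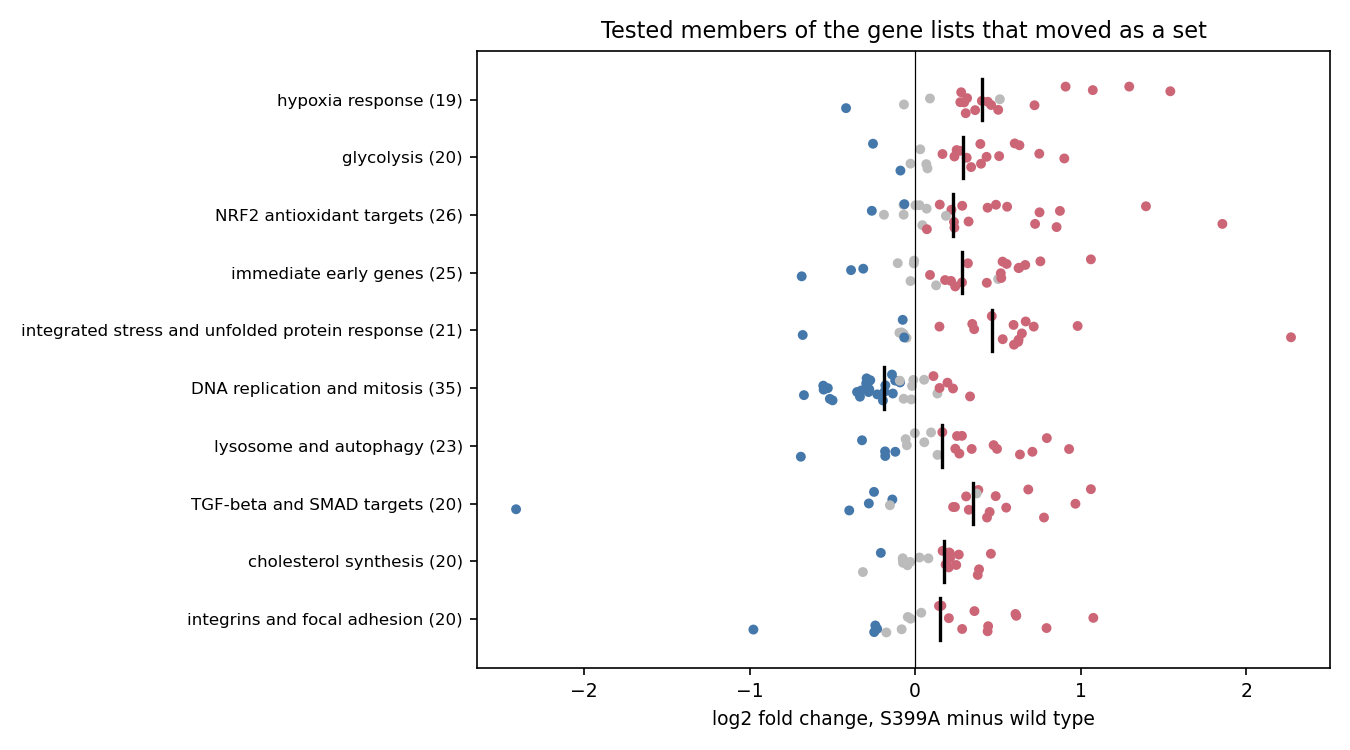
Log2 fold changes (S399A minus wild type, x axis) of the tested members of the 10 gene lists that moved as a set, with the number of tested members in brackets. Red points rose, blue points fell and grey points did not pass the test; black bars are list medians, which lie above 0 for 9 lists and below 0 for DNA replication and mitosis.

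Changed genes were grouped along chromosomes. Chromosome 17 was lower along its whole length in the knock-in cells: of its 629 tested genes 465 fell and 16 rose, with a median log2 fold change of -0.40. Lower blocks also covered 40 to 100 Mb of chromosome 15 (309 genes, 235 fell, median -0.37) and 60 to 110 Mb of chromosome 7 (227 genes, 167 fell, median -0.43), in hg38 coordinates. Others covered 40 to 110 Mb of chromosome 10 (273 genes, 197 fell, median -0.33) and 0 to 30 Mb of chromosome 20 (110 genes, 74 fell, median -0.33). Higher blocks covered 130 to 160 Mb of chromosome X (91 genes, 57 rose, median 0.38), 40 to 80 Mb of chromosome 12 (238 genes, 145 rose, median 0.25) and 110 to 160 Mb of chromosome 3 (177 genes, 100 rose, median 0.21).

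Genes with the smallest adjusted p in these blocks included, on chromosome 17, TOP2A, NT5C3B (127 ± 1.9 to 58.5 ± 1.3 TPM) and POLDIP2 (251 ± 4.1 to 107 ± 4.7 TPM). On chromosome 15, ANP32A fell from 260.4 ± 3.1 to 153 ± 0.99 TPM and RCN2 from 112 ± 2.4 to 64.4 ± 1.3 TPM. On chromosome 7, PEG10 fell from 302 ± 13 to 139 ± 3.2 TPM and MEPCE from 69.8 ± 1.2 to 39.1 ± 1.6 TPM. On the end of chromosome X the lysosomal sulfatase IDS rose from 129 ± 3.8 to 252 ± 8.3 TPM and the actin crosslinker FLNA from 837 ± 3.5 to 1377 ± 49.6 TPM. Some genes went against their block: DDIT4 rose within the lower block of chromosome 10, and the Notch ligand JAG1 rose from 63.8 ± 1.9 to 159.7 ± 6.7 TPM within that of chromosome 20.

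Of 280 windows of 10 Mb, 37 were lower and 28 higher than random sets of as many tested genes (10000 sets, Benjamini-Hochberg adjusted permutation p under 0.05). The lower windows held 19.4% of the tested genes and 42.5% of those that fell. They also held 7 of the 13 telomerase and c-MYC targets that fell, 6 of 11 interferon-stimulated genes and 5 of 10 sphingolipid genes. The same held for 4 of 8 genes of fatty acid synthesis and 4 of 5 of fatty acid oxidation. Several of these shares were near the 42.5% of all genes that fell. Some lists not named here had shares as large, such as 4 of 8 extracellular matrix genes, 2 of 3 p53 targets and 2 of 2 glycolysis genes. Shares were smaller for some lists, such as 3 of 11 YAP and TEAD targets and 2 of 6 NF-kB and cytokine genes. They were also smaller for S1P receptors and transporters (1 of 4), AMPK genes (1 of 4) and stress-response genes (0 of 3). Higher windows held all 4 epithelial genes that rose, 4 of 8 of oxidative phosphorylation, 5 of 12 of lysosome and autophagy and 5 of 16 NRF2 targets. They held 1 of 15 hypoxia genes, 2 of 16 immediate early genes and 1 of 13 TGF-beta targets that rose. ITGA5, AKR1C3, IDI1, MAP1LC3B, VLDLR and SPINT2 are among the risen genes in higher windows. The windows were called lower or higher from the same fold changes, so some excess of fallen or risen genes in them is built in. The window that contains SPHK2, 40 to 50 Mb of chromosome 19, was among the lower ones (186 genes, median -0.13). Of 15 tested genes on the list of SPHK2 neighbours 2 rose and 5 fell (camera adjusted p = 0.49), with MAMSTR lower (-0.79), GRWD1 lower (-0.40), CA11 higher (0.71) and PLEKHA4 higher (0.41). Centred on the median of their window, 11 named genes no longer passed. The log2 fold change came close to 0 for COX5A (-0.42 to -0.015), FASN (-0.23 to 0.011), ETFA (-0.38 to 0.029), PRKAA1 (-0.10 to -0.032) and PRKAA2 (0.20 to 0.048), with limma adjusted p from 0.36 to 0.81. It shrank but stayed further from 0 for FLCN (-0.42 to -0.11), NLRC5 (0.23 to 0.10), SPNS2 (-0.67 to -0.29) and ASAH2 (-0.72 to -0.29), with adjusted p from 0.19 to 0.36. It moved less for TAGLN (-0.48 to -0.32, adjusted p = 0.078) and S1PR1 (-0.51 to -0.47, adjusted p from 0.044 to 0.064). No DNA measurement was analysed here, and the labels give no information on how many edited clones the knock-in libraries represent.

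**Figure D4:**
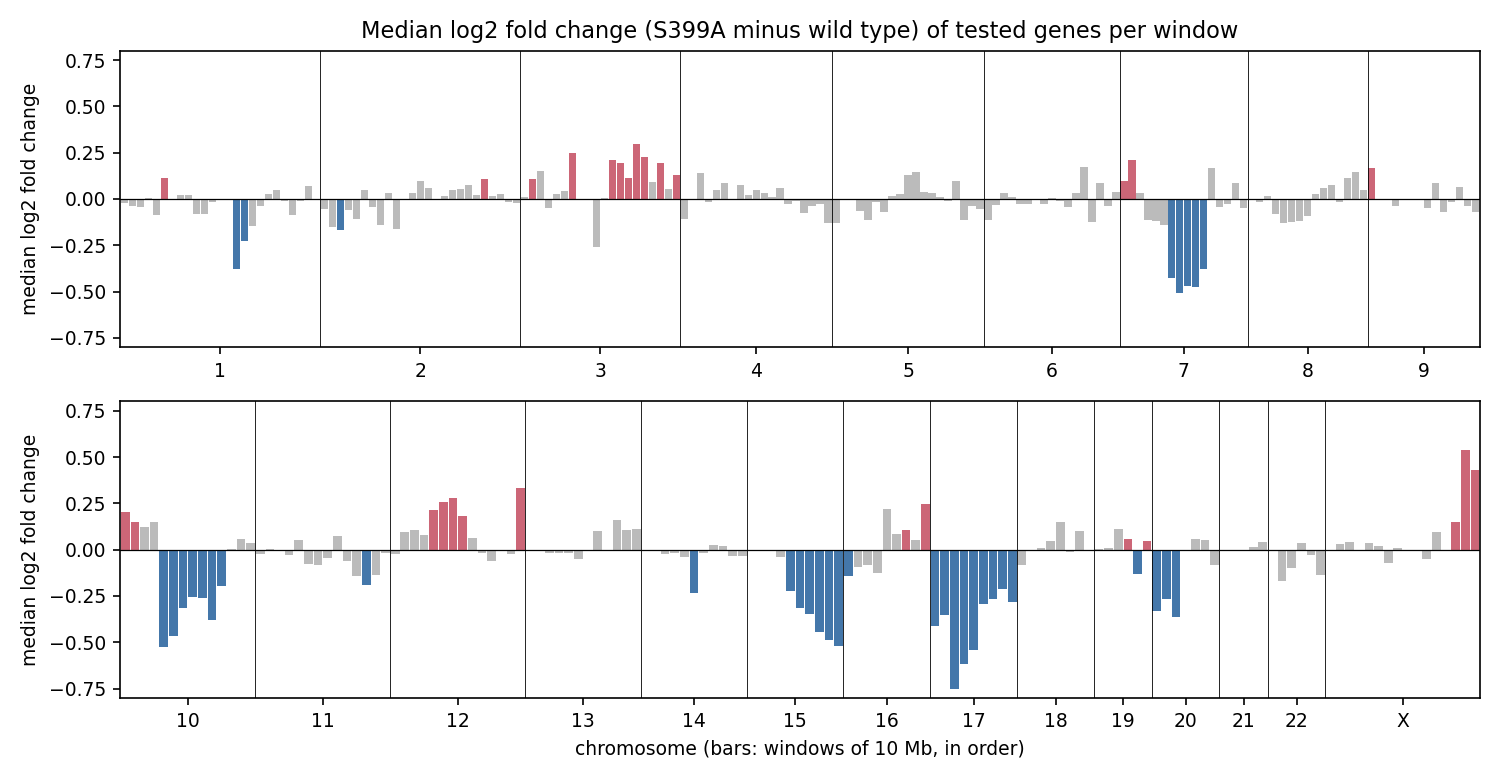
Median log2 fold change (S399A minus wild type) of the tested genes in each 10 Mb window, in order along chromosomes 1 to 22 and X; blue windows were lower, red windows higher and grey windows not different from random sets. Runs of blue windows cover chromosome 17 and parts of chromosomes 7, 10, 15 and 20, and red windows cover the end of chromosome X.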

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

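Alternatives that centre genes on chromosome windows, leave out moved windows, regress out GC content and length or use recovered reads were chosen after seeing the data. The count of changed genes stayed between 4263 and 6339 under the alternatives run, with 1 exception: genes outside the moved windows gave 3488, of which 1774 fell, because 7737 genes were tested. Leaving out 1 library gave 5090 to 5440 changed genes (2145 to 2278 rose, 2930 to 3253 fell). Genes at 2-fold numbered 492 with a pseudocount of 0.1 (149 rose, 343 fell) and 102 with 5 (47 rose, 55 fell), since the pseudocount shrinks low genes. They numbered 202 with a filter of 5 TPM (134 fell) and 194 outside the moved windows (119 fell), where fewer genes were tested, and 519 with limma-voom on recovered reads (162 rose, 357 fell), for which the cause was not tested; without 1 library they numbered 268 to 312 (82 to 109 rose, 165 to 230 fell).

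Lists that moved numbered 0 when camera, asking the same question, estimated the correlation between genes, so the list calls rest on the preset correlation. They numbered 25 with fry, which asks another question, 10 to 12 without 1 library, and 9 to 13 otherwise. Windows of 10 Mb that moved numbered 62 to 73 across the alternatives, of 276 to 292 windows, and 62 to 67 without 1 library; 71 of 411 windows of 5 Mb and 46 of 155 windows of 20 Mb moved. SPHK2 stayed lower and called in all alternatives, with a log2 fold change from -0.46 to -0.32 and from -0.46 to -0.37 without 1 library. The first principal component held 71.6% of the variance with a filter of 5 TPM, 49.9% with no filter, 48.4% and 71.3% with pseudocounts of 0.1 and 5, 59.8% with quantile normalization, 56.0% when centred on windows, 56.9% outside moved windows, 66.0% with recovered reads and 63.4% to 65.2% without 1 library; the cause was not tested. Samples share only a replicate number, since deviations of the same-numbered libraries correlated at -0.068, -0.045 and -0.023; a replicate block gave 5385 changed genes, 5277 of them shared.

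Of 138 genes that the naming rule chose beside SPHK2, 123 kept direction and call under all alternatives run on them. Centring on windows turned ETFA to 0.029 and FASN to 0.011, neither called, since both lie in lower windows, and 13 others lost the call under at least 1 alternative. The planned count-model fits were not run because the table holds TPM, and leaving out mitochondrial genes moves nothing because none is listed. Depth limits genes under 10 reads per library, which include the 6 named microRNA genes. In the wild-type libraries they also include TFF1, IL13RA2, S100P, TCN1, PAPPA2 and AKR1B10. In the knock-in libraries they include SPANXC, CLDN3 and OAS1, among others. The size of the fold change of these genes is therefore uncertain.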

Other observations

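S100 genes rose together in the knock-in cells, a family tested only after the data were seen. Of 12 tested S100 genes 10 rose and 0 fell, with a median log2 fold change of 0.52 (camera adjusted p = 0.00095 over 24 families; adjusted p = 0.30 with an estimated correlation). S100A2, a calcium-binding protein, rose from 23.8 ± 1.1 to 91.03 ± 3.8 TPM and S100A6 from 1731 ± 72 to 2689 ± 65 TPM, although both lie at 140 to 160 Mb of chromosome 1, where 89 of 164 tested genes fell. The nuclear pore family had 11 of 20 genes lower and 0 higher, with no call as fitted (camera adjusted p = 0.20; 0.51 with an estimated correlation; 0.0034 when centred on chromosome windows). The proteasome family, with 17 of 40 genes higher and 11 lower, likewise had no call as fitted (0.30; 0.51 with an estimated correlation) and 0.0034 when centred.

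Amino acid transport and serine metabolism genes outside the fixed lists were chosen after their values were seen. SLC7A5, the large neutral amino acid transporter, rose from 256 ± 1.6 to 565 ± 7.7 TPM, and SHMT2, a mitochondrial enzyme of serine use, rose from 328 ± 9.3 to 573 ± 14 TPM (limma adjusted p = 1.5e-07 and 1.2e-06). Both lie in windows that were higher as a whole, with medians of 0.25 on chromosome 16 and 0.26 on chromosome 12. Solute carrier genes as a family had no call, with 47 of 199 tested genes higher and 54 lower (camera adjusted p = 0.89).

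The tests below were chosen after their results were seen, except the comparison of high and low genes of at least 10 TPM and the GC and length test of the hypoxia list. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 5842 changed genes, 311 at 2-fold, 10 lists and 65 windows, and the highest of the other splits gave 3, 3, 3 and 58; for each of these, 1 of the 10 splits, the real one, gave a result as large. The other splits exchange 1 library, keep part of the real difference between their groups and put the rest into the spread within groups. Few called genes in them are therefore built in and do not measure chance. Their largest window median lay 0.246 from that of all genes, against 0.712 for the real split.

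The first pattern is the shift of neighbouring genes along chromosomes. The tables argue against GC content and length. With both regressed out, 60 of the 65 windows still moved the same way, 5 lost the call and 8 others gained it. Each window is compared with sets of tested genes from the same fit. Scaling shared by a whole library therefore largely cancels, and the window test cannot judge it. With quantile normalization, which gives all libraries the same distribution of levels, 64 of the 65 windows still moved the same way. That result argues only against scaling that depends on expression level. In the lower blocks of chromosomes 7, 10, 15, 17 and 20, of 1548 genes the 1151 of at least 10 TPM fell by similar amounts above and below their median level (medians -0.36 and -0.38, difference 0.027, 95% bootstrap interval -0.0054 to 0.060), as a difference in copy number between the cell populations would give. Over all 1548 genes the difference was 0.040 (0.0020 to 0.068), and 0.091 (0.0498 to 0.13) with recovered reads, on which genes outside the moved windows also differed by 0.0745 (0.061 to 0.089). The 397 genes under 10 TPM fell further with recovered reads (median -0.56 against -0.37 for the rest). Outside the moved windows genes under 10 TPM were also lower on that scale (-0.090 against 0.0076), so part of this gap is not particular to the blocks. On log2(TPM + 1) the gap in the blocks was smaller (-0.42 against -0.37). Copy number may be a candidate explanation for the blocks, with the remaining extra fall of genes under 10 TPM left unexplained. The comparison of high and low genes cannot tell copy number from any other cause that lowers all genes of a region alike. An effect of the edit itself stays open: the highest chromosome 17 median among the knock-in libraries was -0.359, so all 3 share the shift, and the edit and the history of the edited cells cannot be told apart in this design.

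The second pattern is the rise of the hypoxia list. The glycolysis and stress lists also rose, and GC content and length were not tested for them. The chromosome blocks do not account for the hypoxia rise, since that list kept a median of 0.381 when each gene was centred on its 10 Mb window, nor do GC content and length, with a median of 0.393 once both were regressed out. Growth conditions that differed between the cultures, such as density or age of the medium, could give the same rise: the lowest hypoxia list median among the knock-in libraries was 0.348, and conditions and genotype cannot be told apart because the labels give no culture conditions per library.

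The third pattern is the lower SPHK2 transcript. SPHK2 stayed at -0.32 and called when centred on the median of its 10 Mb window. That fit does not measure how far genes of the window differ from each other, and their quartiles were -0.34 and 0.067. It therefore cannot decide whether a shift of the chromosome region is the whole cause. A shift of its immediate neighbours may contribute and stays open: the 4 tested genes within 100 kb had a median of -0.158 and ranged from -0.79 to 0.71, which is too few and too mixed to decide. Reads shared with the overlapping genes RPL18 and DBP could also contribute, which was not tested. An effect of the edit on the transcript was not tested separately.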
